A study of Drosophila melanogaster with 16 samples.

How the data were processed

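RNA of OSS cells, a Drosophila ovarian somatic cell line, was sequenced after electroporation of a 10 cm plate with 500 pmol of siRNA against GFP, piwi, the Paf1 gene or both and 6 days of culture, from NUN pellets and from cytoplasm lysates. Per the labels, the libraries were strand-specific, and the processing notes name Bowtie without a version. The deposited files hold, for 24995 transcript models in each of 16 libraries, raw counts that the authors made of uniquely aligned reads per 5' untranslated region, CDS, 3' untranslated region and locus, for each strand and for both together, with no normalization. A further set of deposited counts covers all alignments, where a read that aligns at several places counts at each, and a read can count in several models and regions. The authors also deposited RPM values, reads scaled to a library total of their own with reads of several alignments weighted, which were not used here. The remaining deposited columns, per the file headers, are coordinates and lengths in bases. The genome build is not given.

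The measure was the unique count on the CDS in the column that holds each gene's own RNA: that column took 95.4% of CDS counts for genes on the plus strand and 96.0% for genes on the minus strand. The CDS was used because its length was the same in all files (0 models differed), while the 3' untranslated window differed between libraries in 18480 models and the locus start in 17786. The model with the longest CDS stood for each of 14229 genes, of which 4629 had several models and 13892 had a CDS. Names of the fixed lists were matched through a later annotation, used for names only: 10913 symbols matched, 3226 matched through an older name and 90 did not match. An older name that several genes have held takes the first match, so a few members can be misassigned.

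Tests were run with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, a robust quasi-likelihood F test, 1 coefficient per group) and p-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. The NUN fit held 8 libraries and 8233 genes (biological coefficient of variation 21.2%, TMM factors 0.97 to 1.05), the cyto fit 8 libraries and 5715 genes (32%, 0.65 to 1.37), and the fit across fractions 16 libraries and 7983 genes (25.1%, 0.37 to 1.83). Each comparison set 2 libraries against 2, with the spread taken from all groups of the fit. The 3 knockdowns were compared with siGFP in each fraction, the double knockdown with each single knockdown, the double knockdown with the sum of both single changes, NUN with cyto in siGFP, and the siPIWI and siPAF1 changes between fractions. Comparisons with siGFP share its libraries and so share their chance values. Levels are CPM on TMM-scaled library sizes. A gene with 0 counts in a group was given a floor of 3 counts over the group, and a gene with 3 counts an exact 95% counting interval of its ratio. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

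Gene lists were fixed by name: 23 lists, of which 4 of transposon families had 0 names among the rows, the mitochondrial list 0 names, and the list of nuclear-retained RNAs 8 names of which 0 passed the count filter. The other 17 were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Of 170 such tests in the knockdown comparisons within a fraction, camera with the preset correlation called 18, and the estimated correlation and the directional test of fry called 0. The mixed test of fry, which lets members move either way, called 9. In 48 of 255 tests over all comparisons the median, the mean and the test of a list differed in sign, and the lowest camera adjusted p among these was 0.31. No camera call changed the sign of its median with DESeq2 size factors or with the 20 most abundant genes left out of the library sizes.

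Genes were named by a rule: the siRNA targets, the 5 that rose and the 5 that fell most among those past the threshold with a mean of at least 20 counts and no overlap between the groups (3 and 3 where the comparison was not with siGFP), and from each list up to 4 members past the threshold or, with none, the 2 most abundant. The comparisons, tests, lists, naming rule and first alternatives were set before the data were examined. Simulated data took each gene's dispersion from the fit of all libraries of the fraction. Changes were placed in the siPIWI group, only in genes with a mean of at least 20 counts. In NUN, 22 of 100 such genes with a log2 change of 1 and 90 of 100 with a change of 2 were called. There were 8 false calls among 8003 genes. In cyto 8 and 64 of 100 were called, with 2 false calls among 5485.

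Alternatives tried were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no count filter, and a strict filter of 10 counts in every library of at least 2 groups. Others were the 20 most abundant genes left out of the library sizes, the library number as a replicate block, all alignments, and both strands together. Further ones were 16 libraries in 1 fit, only the 2 groups compared, and each library left out in turn. Added later were the locus window, a term for the length of the 3' windows, cyto fits restricted to genes higher in cyto, and cyto fits without 2 libraries. Counts on the opposite strand of the CDS were tested separately with the sense library sizes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Transposon results are not analysed here, since the tables hold no transposon rows.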

Results

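RNA was sequenced from OSS cells, a line of cultured ovarian somatic cells of Drosophila melanogaster, after electroporation with siRNA against GFP (siGFP, the control), against the gene piwi (siPIWI), against the Paf1 gene (siPAF1) or against both (the double knockdown). Cells were grown for 6 days and split into a pellet that the labels call NUN, an abbreviation they do not spell out, and a cytoplasm lysate (cyto). Each of the 8 groups had 2 libraries, numbered OSS_146 and OSS_147, which gives 16 libraries of strand-specific RNA. Nothing in the labels says whether libraries OSS_146 and OSS_147 came from separate cultures, so every p-value measures the spread between these libraries. Unique counts on the coding sequences (CDS) in the sense direction ranged from 2080840 to 4623982 per NUN library and from 663903 to 1759169 per cyto library. Between 9443 and 10903 genes had a count in a NUN library, against 7417 to 8494 in a cyto library. The 20 most abundant genes took 10.6% to 15.2% of the NUN counts and 32.1% to 45.8% of the cyto counts. Levels below are normalised read counts (CPM, scaled by TMM library sizes) as mean ± SD with n = 2 libraries per group, changes are log2 fold changes ± SE from edgeR, and p is adjusted over all genes of the comparison unless stated otherwise. Coordinates are those of the files, whose genome build is not given. Transposon families had no rows of their own in the gene tables and are not analysed here.

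The mRNAs that the siRNAs aim at were measured in every library first. The gene piwi (chromosome 2L, 10982205 to 10987416) encodes the Argonaute protein that carries piRNAs in the nucleus of follicle cells. In cyto its mRNA stood at 288 and 308 CPM in the siGFP libraries, at 86.4 and 42.5 CPM with siPIWI, at 251 and 345 CPM with siPAF1 and at 101 and 36.2 CPM in the double knockdown. In NUN the values were 1060 and 1010 CPM with siGFP, 877 and 592 CPM with siPIWI, 1380 and 1220 CPM with siPAF1, and 1070 and 749 CPM in the double knockdown. The cyto difference of siPIWI from siGFP was -2.18 ± 0.50, with adjusted p = 0.303 over all genes and adjusted p = 0.0074 when adjusted over the list alone (the piRNA pathway list). Without the siPIWI library OSS_146 it passed over all genes at -2.81 (adjusted p = 0.0083), and without the siPIWI library OSS_147 at -1.83 (adjusted p = 0.028). The NUN difference was -0.49 ± 0.25 (adjusted p = 1). The Paf1 gene, listed as atms (chromosome 3R, 601323 to 603213), encodes a subunit of the Paf1 complex, which travels with elongating RNA polymerase II. In cyto atms mRNA stood at 167 and 172 CPM with siGFP, at 105 and 93.8 CPM with siPIWI, at 10.7 and 5.96 CPM with siPAF1 and at 11.7 and 9.65 CPM in the double knockdown. It fell by 4.28 ± 0.48 on the log2 scale with siPAF1 in cyto (adjusted p = 5.89e-05) and by 3.94 ± 0.47 in the double knockdown (adjusted p = 0.000146). In NUN atms was at 82.7 and 58.4 CPM with siGFP, at 72.1 and 75.5 CPM with siPIWI, at 26.3 and 18.3 CPM with siPAF1, and at 34.1 and 19.0 CPM in the double knockdown.

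**Figure D1:**
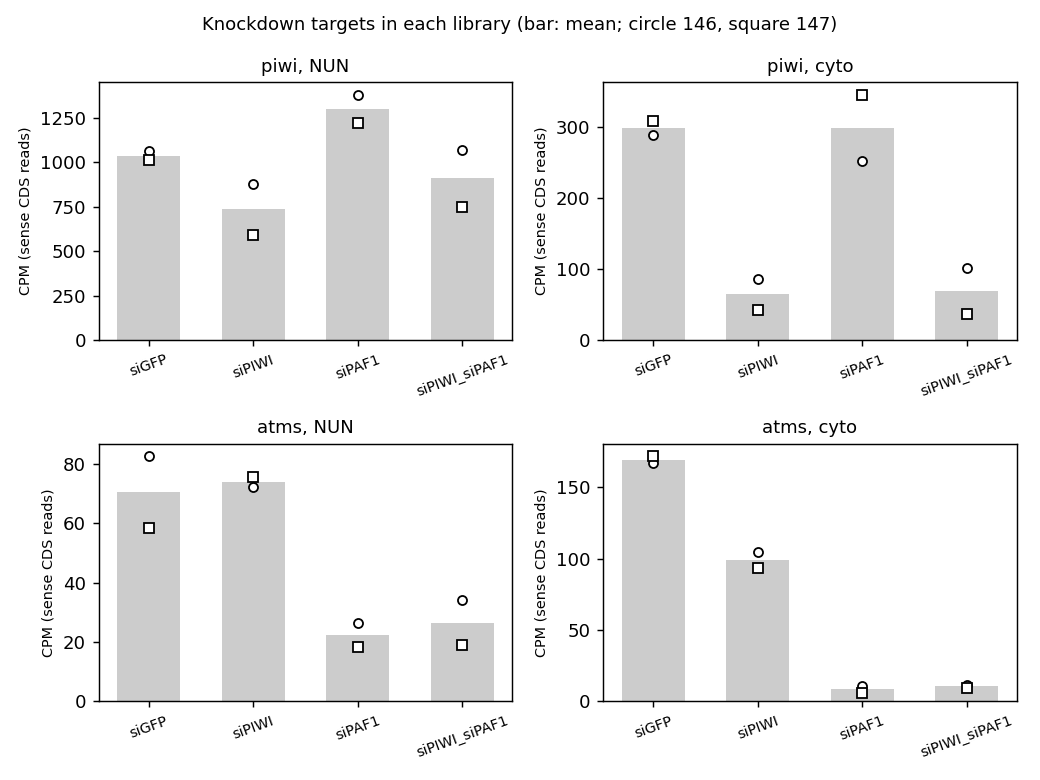
Level of piwi and atms mRNA in CPM in each of the 16 libraries, by group and fraction; bars are means, circles library OSS_146 and squares library OSS_147. In cyto, piwi stands at 101 CPM or less in the 4 libraries that received siPIWI, alone or with siPAF1, and at 251 to 345 CPM in the other 4, and atms stands at 11.7 CPM or less in the 4 libraries with siPAF1.

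The comparison of siPIWI with siGFP in NUN asks which transcripts of the pellet change with siRNA against piwi. Of 8233 genes, 10 rose and 0 fell. The mRNA of dumpy (dp, chromosome 2L, 4479471 to 4591963), which encodes a giant extracellular matrix protein, rose from 45.8 ± 13.7 to 697 ± 163 CPM, a log2 fold change of 3.94 ± 0.40 (adjusted p = 0.0137). The cytochrome P450 gene Cyp28a5 (chromosome 2L, 13977303 to 13979571) rose from 3.45 ± 1.54 to 81.9 ± 44.0 CPM (4.62 ± 0.56, adjusted p = 0.0172). CG30095 (chromosome 2R, 12010989 to 12012082) rose from 1.97 ± 1.5 to 69.5 ± 30.6 CPM (5.04 ± 0.57, adjusted p = 0.0137, but 1.07 with adjusted p = 0.61 when both strands were counted together), and CG13870 (chromosome 2R, 16231350 to 16233384) rose from 1.81 ± 0.652 to 56.8 ± 26.6 CPM (5.0 ± 0.54, adjusted p = 0.0137). CG12691 (chromosome X, 4160130 to 4160702) had 220 counts in the siPIWI libraries against 3 in the siGFP libraries, a ratio of 55.5 after scaling with an exact 95% counting interval of 18.8 to 271 (adjusted p = 0.0372). The 5 remaining calls lie outside the naming rule and were chosen after their values were seen. Of these, Pde6, a cGMP phosphodiesterase gene (chromosome 3R, 10339622 to 10355513), rose by 3.13 ± 0.36 (adjusted p = 0.0137), and Unc-89, which encodes the muscle protein obscurin (chromosome 2R, 19883066 to 19900558), by 3.0 ± 0.40 (adjusted p = 0.0341). The Nimrod-family gene nimC2 (chromosome 2L, 13980146 to 13982952) rose by 3.6 ± 0.50 and the axon guidance gene gogo (chromosome 3L, 20261959 to 20288231) by 1.70 ± 0.24 (adjusted p = 0.0372 for each), and over its whole locus gogo stood at 0.73 (adjusted p = 0.98). CG15572 (chromosome X, 4162734 to 4165116) rose from 2.54 ± 0.258 to 25.4 ± 12.2 CPM (3.34 ± 0.48, adjusted p = 0.0386). Over the locus window Unc-89 (adjusted p = 0.054) and CG15572 (adjusted p = 0.2) also no longer passed, and with the library number as a replicate block CG12691, CG15572, gogo and nimC2 had adjusted p of 0.07 to 0.079. Cyp28a5 and nimC2 are 574 bases apart, and CG12691 and CG15572 are 2031 bases apart. Without the siGFP library OSS_146, the siPIWI library OSS_146 or the siGFP library OSS_147 the count was 0, and without the siPIWI library OSS_147 it was 8, with nimC2 at 3.82 (adjusted p = 0.12) and Unc-89 at 3.25 (adjusted p = 0.071). With any of those 3 libraries left out dp stood between 3.65 and 4.27, with adjusted p of 0.057 to 0.15. On simulated changes of log2 size 1 and 2 at this depth, placed in genes with a mean of at least 20 counts, the test called 22 and 90 of 100 genes.

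**Figure D2:**
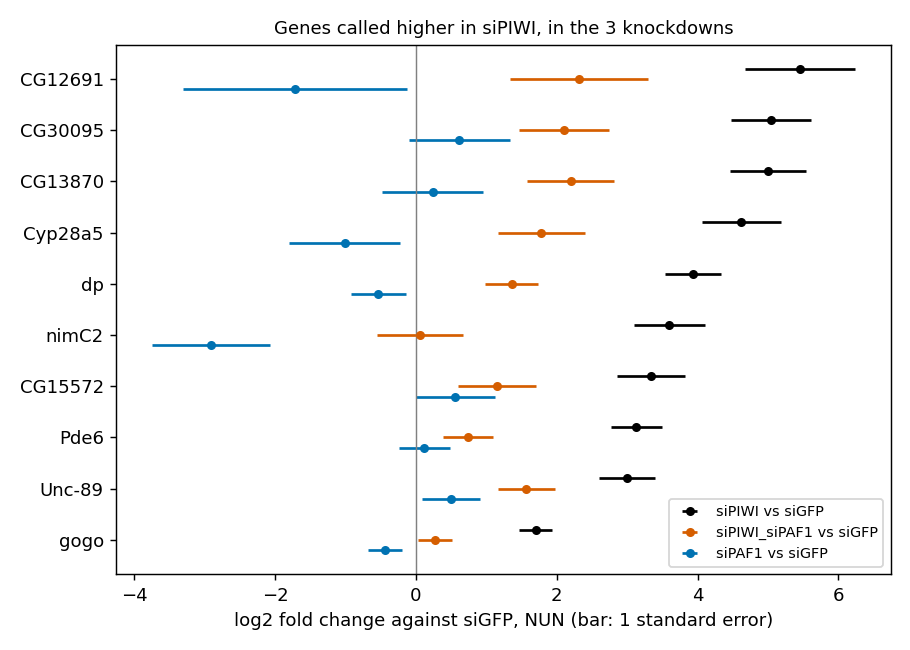
Log2 fold change ± SE against siGFP in NUN of the 10 genes called with siPIWI, in the siPIWI, siPAF1 and double knockdown groups (2 libraries each). Their median was 3.77 with siPIWI and 1.47 in the double knockdown; the 3 comparisons share the siGFP libraries.

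Among the 17 gene lists tested in NUN, 0 members passed with siPIWI over all genes and 1 passed when adjusted over the list alone, the sodium channel gene para at 1.04 ± 0.27 (adjusted p = 0.044 over that list). Here and below, genes that passed only over their list were chosen after their values were seen. The heat shock and protein folding list was higher as a set, with a median of 0.21 and 14 of 16 members positive (camera adjusted p = 0.0091, and adjusted p = 0.63 with an estimated correlation). Its most abundant members, Hsp83 at -0.01 ± 0.42 and Hsc70-4 at 0.03 ± 0.45, did not pass. The other 16 lists had camera adjusted p of 0.23 to 0.96. In the piRNA pathway list 22 of 32 members were positive (median 0.08), with Mi-2 at 0.05 ± 0.20. The germline list held tud at 0.03 ± 0.18 and spn-E at -0.04 ± 0.28. The genic piRNA sources were close to 0, with tj (traffic jam) at 2910 ± 1460 CPM against 2860 ± 56.4 CPM and dlg1 at 0.00 ± 0.19. The Paf1 complex list held CG2469, the Ctr9 gene, at 0.18 ± 0.18 and Rtf1 at -0.02 ± 0.24. The RNA polymerase II list held RpII215, the largest subunit gene, at 0.16 ± 0.18 and Set2 at -0.02 ± 0.19. Among the immune and antiviral lists Rel stood at 0.01 ± 0.20, pirk at 0.00 ± 0.32, Stat92E at -0.25 ± 0.20 and Dcr-2 at 0.06 ± 0.19. For DNA damage, cell cycle and histones, Xrp1 was at 0.07 ± 0.34, polo at 0.08 ± 0.18 and His3.3B at 0.13 ± 0.32. RpL4 of the ribosomal list was at 0.28 ± 0.35. Follicle cell identity had a median of -0.12 with ptc at -0.02 ± 0.22, and the ecdysone list a median of -0.12 with Eip75B at 0.23 ± 0.22. Of the markers of other cell types sls was at 0.03 ± 0.18, and kek1 of the growth signalling list was at -0.04 ± 0.24. InR, of the stress and insulin list, was at 0.05 ± 0.23.

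With siPAF1 in NUN the question is which pellet transcripts change with siRNA against the Paf1 gene. The targeted atms mRNA stood at -1.66 ± 0.33 (22.3 ± 5.61 against 70.5 ± 17.2 CPM), with adjusted p = 0.238 over all genes and adjusted p = 0.0029 when adjusted over the list alone. Of 8233 genes 0 rose and 0 fell in edgeR, 839 (10.2%) had an unadjusted p under 0.05, where 5% would be expected by chance, and DESeq2 called 23, of which 9 rose and 14 fell. By DESeq2 atms passed (adjusted p = 0.0098). In all, 6 list genes passed when adjusted over the list alone. Besides atms these were para at 1.80 ± 0.26 (60.3 ± 9.51 against 17.4 ± 3.64 CPM, adjusted p = 0.00073), the immune peptide gene edin at 1.53 ± 0.26 (adjusted p = 0.0014) and the scavenger receptor gene Sr-CI at 1.47 ± 0.37 (adjusted p = 0.016). The others were the peroxidasin gene Pxn at -0.92 ± 0.24 (adjusted p = 0.016) and Hsp68 at 0.81 ± 0.20 (adjusted p = 0.046). Over all genes their adjusted p ranged from 0.11 for para to 0.37 for Pxn. The cell cycle and replication list was lower as a set, with 6 of 34 members positive and a median of -0.29 (camera adjusted p = 0.0025, and adjusted p = 0.5 with an estimated correlation). Its member RnrS was at -0.64 ± 0.32 and polo at 0.04 ± 0.18. The heat shock list was higher, with 11 of 16 members positive and a median of 0.38 (camera adjusted p = 0.0062, and adjusted p = 0.51 with an estimated correlation). The other 15 lists had camera adjusted p of 0.064 to 0.9. Among other members srp was at 0.95 ± 0.35, Xrp1 at 0.94 ± 0.34, Set2 at -0.54 ± 0.19, Stat92E at 0.47 ± 0.20 and Dcr-2 at 0.43 ± 0.19, each with adjusted p of 0.416 or more.

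In the double knockdown of NUN, set against siGFP, the sodium channel gene para (chromosome X, 16357636 to 16421447) rose from 17.4 ± 3.64 to 104 ± 18.1 CPM, a log2 fold change of 2.58 ± 0.27 (adjusted p = 0.0211). It was the only call among 8233 genes in edgeR, where 485 had an unadjusted p under 0.05. Without the siGFP library OSS_146, the siGFP library OSS_147 or the double knockdown library OSS_146 the count was 0, with para at 2.80 (adjusted p = 0.069), 2.37 (0.12) and 2.40 (0.16). It no longer passed with the library number as a replicate block (2.58, adjusted p = 0.1) or with only the compared groups (2.58, adjusted p = 0.69). Without the double knockdown library OSS_147 it was 2. The targets stood at -0.18 ± 0.24 for piwi (adjusted p = 0.992) and at -1.41 ± 0.33 for atms, with adjusted p = 0.398 over all genes and adjusted p = 0.0092 when adjusted over the list alone. When adjusted over the list alone, 5 list genes passed, against 1 over all genes. They were para, atms, Hsp68 at 1.01 ± 0.21 (adjusted p = 0.011), Sr-CI at 1.57 ± 0.37 (adjusted p = 0.014) and the germline gene rhi (rhino) at 1.39 ± 0.29 (adjusted p = 0.014). The heat shock list was higher (14 of 16 members positive, median 0.47, camera adjusted p = 5.8e-06), and the cell cycle list was lower (8 of 34 positive, median -0.27, camera adjusted p = 0.00069). With an estimated correlation both had adjusted p = 0.31. The ribosomal protein list was higher (36 of 40 positive, median 0.26, camera adjusted p = 0.00069, and adjusted p = 0.79 with an estimated correlation). The other 14 lists had camera adjusted p of 0.062 to 0.99. Among their members Set2 was at -0.44 ± 0.19, tefu at -0.53 ± 0.23 and Xrp1 at 0.54 ± 0.34.

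Setting the double knockdown against each single knockdown in NUN asks what the second siRNA adds. Against siPIWI, atms stood at -1.48 ± 0.32, with adjusted p = 0.449 over all genes and adjusted p = 0.0065 when adjusted over the list alone, and piwi at 0.31 ± 0.24. The gene para stood at 1.54 ± 0.25 (adjusted p = 0.13 over all genes and adjusted p = 0.0016 when adjusted over the list alone). All 10 genes that rose with siPIWI had lower estimates in the double knockdown than with siPIWI, with a median of -2.69 and adjusted p of 0.1 to 0.79, so none of these differences passed. A term for the length of the 3' windows, added after the data were seen, let 8 of the differences pass. The median of the 10 genes was then -2.71. Against siGFP their median was 1.47 in the double knockdown and 3.77 with siPIWI; in the double knockdown none of them passed (adjusted p of 0.47 to 1), with nimC2 at 0.06 ± 0.61 and gogo at 0.27 ± 0.24, and the genes had been chosen against the same siGFP libraries. In edgeR 0 of 8233 genes passed against siPIWI, 3.61% had an unadjusted p under 0.05, and DESeq2 called 14. The cell cycle list was lower as a set, with 1 of 34 members positive and a median of -0.28 (camera adjusted p = 3e-07, and adjusted p = 0.13 with an estimated correlation). Camera also called the heat shock list (median 0.21, adjusted p = 0.013), the ribosomal list (median 0.14, 31 of 40 positive, adjusted p = 0.013), the antimicrobial list (median 0.22, 9 of 9 positive, adjusted p = 0.034) and the markers of other cell types (median 0.24, adjusted p = 0.012). With an estimated correlation their adjusted p was 0.78, 0.87, 0.79 and 0.78. Against siPAF1, piwi stood at -0.51 ± 0.24 and atms at 0.25 ± 0.34. No gene passed in edgeR (0 of 8233), 230 had an unadjusted p under 0.05, and DESeq2 called 2. The ribosomal list was higher (34 of 40 positive, median 0.20, camera adjusted p = 0.00087, and adjusted p = 0.67 with an estimated correlation). A test of whether the double knockdown departs from the sum of both single changes called 0 of 8233 genes in edgeR, where 67 had an unadjusted p under 0.05 and DESeq2 called 1. In that test 0 lists passed, the lowest camera adjusted p being 0.073 for growth signalling.

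In cyto, siPIWI against siGFP asks which cytoplasmic mRNAs change with siRNA against piwi. The piwi mRNA itself stood at 64.4 ± 31.0 CPM against 298 ± 14.3 CPM and atms at 99.2 ± 7.60 against 169 ± 3.64 CPM (-0.77 ± 0.40, adjusted p = 0.355). In edgeR 0 of 5715 genes passed, 863 (15.1%) had an unadjusted p under 0.05, where 5% would be expected by chance, and DESeq2 called 0. The 10 genes called with siPIWI in NUN were not among these 5715, so this result does not speak to them. Their cyto counts were low, apart from Pde6 in the siPIWI library OSS_146. Pde6 had 1 and 2 counts with siGFP and 112 (OSS_146) and 6 (OSS_147) with siPIWI. Cyp28a5 had 1 and 0 counts with siGFP and 24 and 6 with siPIWI, and CG15572 had 0 and 0 against 1 and 0. The median of all genes was 0.18. The ribosomal protein list was lower as a set, with 7 of 40 members positive and a median of -0.74 (camera adjusted p = 2.3e-05, and adjusted p = 0.82 with an estimated correlation). Its member RpLP2 was at 30400 ± 2980 CPM against 61700 ± 25900 CPM (-1.02 ± 0.53, adjusted p = 0.35). Adjusted over the list alone, 3 list genes passed: piwi, the dynein light chain gene ctp at 1.81 ± 0.52 (adjusted p = 0.031) and the ovarian transcription factor gene bab2 at 3.35 ± 1.05 (adjusted p = 0.034). Over all genes ctp and bab2 had adjusted p = 0.3. The other 16 lists had camera adjusted p of 0.4 to 0.84. Among their members Hsp60 was at -1.28 ± 0.50, Mlc2 at -1.27 ± 0.48, Mcm3 at -1.03 ± 0.43, AGO2 at 1.06 ± 0.44 and Xrp1 at 1.45 ± 0.59, each with adjusted p = 0.303. The libraries of this comparison were unlike each other in their share of counts on 1389 genes that were enriched in NUN over cyto by a log2 of more than 3. That share was 3.71% in the siPIWI library OSS_146 and 0.86% in the siPIWI library OSS_147, and 2.34% and 0.73% in the double knockdown libraries OSS_146 and OSS_147. It was 0.51% to 1.02% in the siGFP and siPAF1 libraries. Without the siPIWI library OSS_146 edgeR called 28 genes, and without the siPIWI library OSS_147 it called 447. Without a siGFP library the count was 0.

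**Figure D3:**
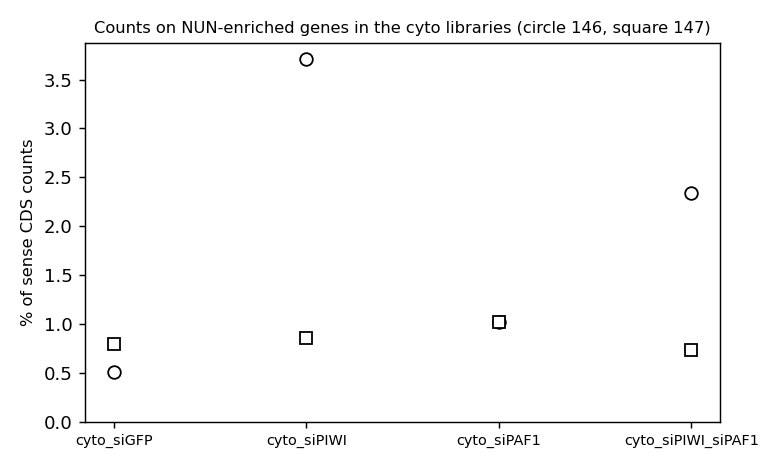
Share of sense CDS counts, in percent, on 1389 NUN-enriched genes in each cyto library, by group and library number. The siPIWI library OSS_146 stands at 3.71% and the double knockdown library OSS_146 at 2.34%, and the other 6 libraries at 0.51% to 1.02%.

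With siPAF1 in cyto, 6 of 5715 genes fell and 0 rose in edgeR. Besides atms (8.35 ± 3.38 against 169 ± 3.64 CPM), the small GTPase gene Rab27 (chromosome X, 1367917 to 1370963) fell from 99.3 ± 43.0 to 15.9 ± 4.27 CPM, a log2 fold change of -2.61 ± 0.48 (adjusted p = 0.0257). CG42259 (chromosome X, 940257 to 941042) fell from 276 ± 142 to 41.2 ± 10.5 CPM (-2.73 ± 0.50, adjusted p = 0.0257) and CG13373 (chromosome X, 371021 to 372224) from 154 ± 57.1 to 24.7 ± 0.134 CPM (-2.63 ± 0.51, adjusted p = 0.0332). Outside the naming rule, and so chosen after their values were seen, CG3457 (chromosome X, 2081855 to 2082748) fell from 43.0 ± 20.3 to 3.57 ± 0.576 CPM (-3.57 ± 0.63, adjusted p = 0.0257) and CG11158 (chromosome X, 13576941 to 13578649) from 40.7 ± 4.22 to 4.33 ± 1.91 CPM (-3.14 ± 0.61, adjusted p = 0.0332). The same 5 genes had lower estimates with siPIWI against siGFP too, between -1.80 ± 0.56 for CG11158 and -0.77 ± 0.52 for CG3457. None of these passed (adjusted p of 0.3 to 0.46). In the double knockdown against siPIWI they stood between -2.03 ± 0.58 for CG3457 and -0.39 ± 0.60 for CG11158, and none passed. The falls can therefore not be taken as particular to siPAF1. With siPAF1 the gene piwi stood at 0.00 ± 0.47. Without the siGFP library OSS_146, the siPAF1 library OSS_146 or the siPAF1 library OSS_147, atms was the only call (a count of 1), and the adjusted p of the other 5 genes rose to between 0.37 and 1. Without the siGFP library OSS_147 the count was 9, with CG11158 at -3.26 (adjusted p = 0.081). DESeq2 called 38 genes, of which 1 rose and 37 fell, with 5 of the 6 among them. Over the locus window Rab27 (adjusted p = 0.068) and CG11158 (adjusted p = 0.069) no longer passed. The count differed between fits: it was 76 with the library number as a replicate block, 159 with only the compared groups and 234 without the siPIWI and double knockdown libraries OSS_146, which lie outside this comparison, and all 6 genes were among each of these. In the gene lists, atms was the only member that passed over all genes, and the muscle actin gene Act57B at 4.40 ± 1.05 (adjusted p = 0.12) passed with it when adjusted over the list alone (adjusted p = 0.0023). By camera none of the 17 lists passed as a set, and the lowest camera adjusted p was 0.28, for heat shock. Mcm3 stood at -1.14 ± 0.43, His3.3B at 1.10 ± 0.47, smt3 (SUMO) at 0.92 ± 0.45, krimp at -0.88 ± 0.42 and tj at -0.93 ± 0.52.

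In the double knockdown of cyto, atms was the only call against siGFP (1 of 5715 genes). It was called without any single library too, with counts of 1 without the siGFP library OSS_146 or the double knockdown library OSS_146, 2 without the siGFP library OSS_147 and 6 without the double knockdown library OSS_147. Of the groups outside the comparison, which enter the estimate of spread and were left out only after seeing the data, leaving out either siPAF1 library gave 1, and leaving out the siPIWI library OSS_146 or OSS_147 gave 153 or 156. With all libraries the count was 73 with the library number as a replicate block, and with only the compared groups it was 84, atms among them in both. The gene piwi stood at -2.08 ± 0.49, with adjusted p = 0.14 over all genes and adjusted p = 0.011 when adjusted over the list alone. In edgeR 648 genes had an unadjusted p under 0.05, and DESeq2 called 43, of which 3 rose and 40 fell. The genes that passed when adjusted over the list alone were 5, against 1 over all genes: piwi, atms, the SUMO-conjugating enzyme gene lwr at 1.79 ± 0.50 (adjusted p = 0.027), Rtf1 of the Paf1 complex at 2.03 ± 0.75 (adjusted p = 0.04) and Act57B at 3.73 ± 1.09 (adjusted p = 0.015). By camera no list passed as a set, the lowest camera adjusted p being 0.082 for ribosomal proteins (median -0.41, 10 of 40 positive). Mcm3 stood at -1.25 ± 0.43, AGO2 at 1.20 ± 0.44 and Xrp1 at 1.62 ± 0.59. Against siPIWI, atms fell by 3.18 ± 0.46 (adjusted p = 0.00379) and was the only call, with piwi at 0.10 ± 0.49. Without the double knockdown library OSS_146 or OSS_147 that count was 0, with atms at -3.28 (adjusted p = 0.25) and -3.07 (adjusted p = 0.18), and without the siPIWI library OSS_146 or OSS_147 it was 3 or 52. Besides atms, krimp at -1.18 ± 0.41, CG11133 at -1.32 ± 0.47 (adjusted p = 0.048 for each) and the titin-like gene sls at -1.81 ± 0.58 (adjusted p = 0.03) passed when adjusted over the list alone. Camera called the ribosomal list higher (35 of 40 positive, median 0.26, adjusted p = 0.012), the cell cycle list lower (median -0.24, adjusted p = 0.026) and the follicle cell list lower (0 of 8 positive, median -0.56, adjusted p = 0.026). With an estimated correlation their adjusted p was 0.87, 0.81 and 0.81, and the siPIWI library OSS_146 of this comparison carried the 3.71% share of counts on NUN-enriched genes. Against siPAF1, piwi stood at -2.07 ± 0.49, with adjusted p = 1 over all genes and adjusted p = 0.011 when adjusted over the list alone, and atms at 0.33 ± 0.51. In edgeR 0 of 5715 genes passed, 51 had an unadjusted p under 0.05, where 286 would be expected by chance, and DESeq2 called 0. The ribosomal list was lower (2 of 40 positive, median -0.18, camera adjusted p = 0.0029) and the RNA polymerase II list higher (24 of 29 positive, median 0.21, camera adjusted p = 0.031). Both had adjusted p = 0.98 with an estimated correlation. The double knockdown library OSS_146 of this comparison carried a 2.34% share of counts on NUN-enriched genes, against 1.02% in each siPAF1 library. For a departure from the sum of both single changes edgeR called 0 of 5715 genes and DESeq2 called 0. There 156 genes had an unadjusted p under 0.05, where 286 would be expected by chance. No list passed, the lowest camera adjusted p being 0.052 for ribosomal proteins.

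NUN and cyto were compared in the siGFP libraries to show which transcripts each fraction holds. Of 7983 genes 2928 were higher in NUN and 2414 were higher in cyto, and leaving out a library gave 4372 to 4941 in all. The median of all genes was 0.55, and 0.67 with DESeq2 size factors. Both scalings assume that most genes do not differ, so this shift of 0.12 does not measure the uncertainty of the scale between fractions. The counts of genes higher in either fraction and the fold values rest on that assumption. CPM above were scaled within a fraction and cannot be compared across fractions: piwi stood at 1030 CPM in NUN and 298 CPM in cyto with siGFP. The nicotinic acetylcholine receptor gene nAcRalpha-34E had 1744 counts in NUN and 0 in cyto, at least 57.1-fold higher in NUN for a floor of 3 counts over the group, which covers counting error only. On that floor Ir47a was at least 41-fold and CG11635 at least 32.4-fold higher. In the other direction CG12400, which encodes a mitochondrial complex I subunit, was 1570-fold higher in cyto, RpLP2 1060-fold and RpL38 855-fold. All 40 ribosomal protein genes tested were lower in NUN, with a median of -6.93 (camera adjusted p = 3.6e-22, and adjusted p = 0.6 with an estimated correlation). Of the follicle cell identity genes 18 of 20 were higher in NUN, with a median of 3.77, or 3.22 with the 4 genes without cyto counts at their bound (camera adjusted p = 0.00018, and adjusted p = 0.6 with an estimated correlation). In the ecdysone list 13 genes were higher and 2 lower (median 3.55, camera adjusted p = 0.015, and adjusted p = 0.6 with an estimated correlation). In the growth signalling list 12 of 16 were higher and 0 lower, in the markers of other cell types 8 higher and 1 lower, and all 3 genic piRNA sources (tj, brat and dlg1) were higher. The RNA polymerase II list had 15 higher and 7 lower, JAK/STAT and antiviral RNAi 7 and 3, DNA damage 8 and 2, the germline list 6 and 3, and the stress and insulin list 10 and 5. The cell cycle list had 12 higher and 8 lower, heat shock 5 and 6, and the piRNA pathway 9 and 11. Histone genes had 1 higher and 4 lower and antimicrobial genes 2 and 5. In the Paf1 complex 1 was higher and 3 lower, among them atms at -2.83 ± 0.36 (adjusted p = 3.14e-07). Adjusted over the list alone, the counts were the same in 16 lists, and in the antimicrobial list 6 genes in place of 5 were lower. The gene piwi stood at 0.23 ± 0.44 (adjusted p = 0.652).

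Whether a knockdown acted differently in the fractions was tested over 16 libraries. For siPIWI 0 of 7983 genes differed in edgeR, 733 had an unadjusted p under 0.05 and DESeq2 called 0. The ribosomal protein list had a higher siPIWI change in NUN than in cyto (33 of 40 positive, median difference 0.81, camera adjusted p = 6.3e-08) and the follicle cell list a lower one (3 of 20 positive, median -1.22, camera adjusted p = 0.0058), both with adjusted p = 0.95 with an estimated correlation. The cyto side of this test includes the siPIWI library OSS_146 with its 3.71% share of counts on NUN-enriched genes. Adjusted over the list alone, bab2 was the only gene that passed for siPIWI. For siPAF1 0 genes differed in edgeR, 410 had an unadjusted p under 0.05 and DESeq2 called 3. No list passed for siPAF1, the lowest camera adjusted p being 0.4, and adjusted over the list alone atms was the only gene that passed. DESeq2 size factors moved the median of all genes from -0.24 to -0.09 for siPIWI and from -0.09 to 0.10 for siPAF1 and kept the direction of both ribosomal and follicle cell medians, at 0.97 and -1.06.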

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

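The measure of the opposite strand, and all tests of the double knockdown pattern and of the cyto library in doubt, were chosen after the result was seen; of the tests of opposite-strand counts in siPIWI, 3 were set before their results were seen and the test on a pair of libraries kept out of the choice was set after.

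Counts on the strand opposite to the CDS lay outside the comparisons of sense RNA, and they changed in the knockdowns. With siPIWI in NUN 46 of 3325 genes rose and 0 fell, and 180 had an unadjusted p under 0.05, where 166 would be expected by chance. The median over all tested opposite strands was -0.27 here, -0.20 with siPAF1 and -0.28 in the double knockdown, all against siGFP in NUN, and rises and falls were counted without a correction for it; with scaling factors from the opposite strand itself the counts of changed genes were 51, 70 and 66. In the simulation of this comparison 7 of 3125 unchanged genes were called. Examples, chosen after their values were seen, are CG30115 (chromosome 2R, 14441624 to 14499260), whose opposite strand rose from 5.0 and 4.05 CPM to 140 and 117 CPM (log2 fold change 4.83 ± 0.51, adjusted p = 6.7e-06) with its sense strand at -0.30, and the adjacent genes CG31233, CG31198 and CG42335 on chromosome 3R (17575575 to 17595023) at 4.83 ± 0.74, 5.04 ± 0.58 and 5.01 ± 0.54. On chromosome 3L CG6034 (17738273 to 17739960) stood at 5.90 ± 0.67 and its neighbour Adgf-B (17741933 to 17743688), an adenosine deaminase-related growth factor gene, at 4.89 ± 0.71. Without the siGFP library OSS_146 the count was 24, without the siPIWI library OSS_146 13, without the siGFP library OSS_147 20 and without the siPIWI library OSS_147 26.

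For the siPIWI pattern, leakage of the genes' own RNA to the other strand is argued against by the 27 genes that were also tested in sense: their opposite strand moved by a median of 2.7 more than their sense strand, in 27 of 27, and 0 of them changed in sense. A single siPIWI library is argued against as well. All 26 genes called without the siPIWI library OSS_147 lay above both siGFP libraries in it, against 19.1% of the other 4492 genes tested in that fit, but these siGFP libraries had served in the choice of the genes, which favours this outcome. With both the siPIWI and the siGFP library OSS_147 kept out of the choice, 12 genes were called, and 12 of 12 were higher in the siPIWI than in the siGFP library OSS_147, by a median log2 difference of 3.99, against 40.2% of the others (Fisher's exact p = 1.8e-05). With the OSS_146 pair kept out 3 genes were called, and 3 of 3 were higher in it. What stays open is RNA of an annotated gene on the other strand for the 12 genes that overlap such a model, 26.1% of the 46 against 47.3% of the others (Fisher's exact p = 0.0044). Among the 12, CG34273 and Cyp313a1 lie inside Pde6 and rk overlaps nimC2, each on the other strand. Both Pde6 and nimC2 rose in sense with siPIWI in NUN, so their RNA could account for the counts on CG34273, Cyp313a1 and rk. The other 34 overlap none, and a candidate explanation for these, left untested, is transcription from sequences missing from the gene table, transposons among them. Several of the 46 genes lie next to each other on the same strand, such as CG9316, CG9317 and CG9318 on chromosome 2L. Genes are therefore not independent replicates, and the counts and Fisher's exact p-values here make no allowance for it.

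With siPAF1 in NUN 46 genes changed on the opposite strand, of which 18 rose and 28 fell. The opposite strand of ft, the protocadherin gene fat (chromosome 2L, 4198402 to 4217852), rose from 50 and 60.4 CPM to 575 and 457 CPM (3.22 ± 0.37, adjusted p = 5e-05), and those of its neighbours CG3702 and CG3714 by 3.80 ± 0.60 and 2.23 ± 0.40. That count was 1 without the siGFP library OSS_146, 22 without the siPAF1 library OSS_146, 126 without the siGFP library OSS_147 and 407 without the siPAF1 library OSS_147. In the double knockdown 23 genes changed (15 rose, 8 fell), with ft at 3.44 ± 0.38, and the count was 1 without the siGFP library OSS_146, 7 without the double knockdown library OSS_146 and 35 without the siGFP library OSS_147. Between the double knockdown and siPIWI 35 genes differed (15 higher, 20 lower), with CG30115 at -2.90 ± 0.45. That count was 0 without the siPIWI library OSS_146, 21 without the double knockdown library OSS_146 and 19 without the siPIWI library OSS_147. Between the double knockdown and siPAF1 6 genes differed (5 higher, 1 lower). In cyto 3 of 93 genes fell with siPAF1 and 3 in the double knockdown, where the medians over all 93 were -0.57 and -0.53.

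The 10 genes that rose in sense with siPIWI in NUN lay lower in the double knockdown, by a median of -2.69. Choice of the genes on the same libraries is argued against, since the 8 genes called without the siPIWI library OSS_147 stood lower in the double knockdown than in that library by a median of -2.02, in 8 of 8. The libraries were also split by the length of their 3' windows. All 10 genes were lower in the double knockdown than with siPIWI, by a median of -3.35 between the long-window libraries and -1.71 between the short ones. The counts were taken on the CDS, so the window length itself cannot change them, and the split can only mark another difference between the libraries. The pairs cannot decide on such a difference, since window lengths differ within them. They were 441.8 bases with siPIWI against 268.1 in the long pair, and 150.1 against 185 in the short pair. The 10 genes had also been chosen as high in these siPIWI libraries, which favours this outcome. A term for the split decides nothing here, as each group holds 1 library of either length. A weaker knockdown of piwi in the double knockdown stays open, with piwi mRNA 0.31 ± 0.24 higher in NUN and 0.10 ± 0.49 higher in cyto. A need for Paf1 in the rise of these genes also stays open, so the pattern could come from either.

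The cyto siPIWI library OSS_146 had 3.71% of its counts on NUN-enriched genes, against 0.86% in the siPIWI library OSS_147. The double knockdown libraries, which also received siPIWI, had 2.34% (OSS_146) and 0.73% (OSS_147), and no library without siPIWI exceeded 1.02%. The Piwi knockdown as the whole cause is argued against by the 0.86% and 0.73%, which lie within the 0.51% to 1.02% of the siGFP and siPAF1 libraries, but an effect of siPIWI in the OSS_146 cultures alone stays open. NUN RNA carried into the lysate of the siPIWI library OSS_146 remains a candidate explanation. Over 1389 NUN-enriched genes the excess in that library followed the NUN level (Spearman correlation 0.82 across genes, which are not independent replicates), and 1110 of them were in excess. These genes had been chosen as low in the siGFP cyto libraries, which favours low shares there. Opposite-strand shares of CDS counts were 0.76% (OSS_146) and 0.63% (OSS_147) with siPIWI. They were 0.36% to 0.47% in the other cyto libraries, the double knockdown among them, so OSS_147 also stood apart by that measure.

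For siPIWI, the change of the ribosomal protein list differed between NUN and cyto (camera adjusted p = 6.3e-08) and so did that of the follicle cell list (camera adjusted p = 0.0058), and neither held with an estimated correlation (adjusted p = 0.95 for each).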

How the results depend on the processing

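The locus window, the term for the 3' window length, the fits on genes higher in cyto and those without the cyto siPIWI and double knockdown libraries OSS_146 were chosen after seeing the data. Neither DESeq2 size factors nor leaving the 20 most abundant genes out of the library sizes moved a count of genes by more than 1.5 times. The planned change of pseudocount, the filter for normalized values and all transposon results were not run, since the files hold counts and no transposon rows. Where a count moved, the cause was not tested unless stated.

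In NUN, counts for siPIWI (10), siPAF1 (0) and the double knockdown (1) against siGFP became 16, 23 and 18 with the DESeq2 Wald test and 38, 196 and 81 with no filter. The 10 siPIWI genes were all among the 16. For the double knockdown against siPIWI (0), against siPAF1 (0) and for departure from the sum (0), the Wald test gave 14, 2 and 1, and no filter 35, 24 and 5. Both strands together gave 19 for siPIWI, 4 for the double knockdown and 2 for it against siPIWI. The locus window gave 3 for siPAF1 and 6 for the double knockdown, and 16 libraries in 1 fit gave 3, 2 and 6 for siPAF1, the double knockdown and that against siPIWI. The term for window length gave 18, 40 and 20 for the 3 knockdowns and 15 for the double knockdown against siPIWI. With only the compared groups the double knockdown gave 0 and against siPIWI 7.

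In cyto, counts for siPIWI (0), siPAF1 (6) and the double knockdown (1) became 5, 42 and 21 with no filter, and the Wald test gave 38 and 43 for the last pair. All alignments gave 14 for siPAF1. The locus window gave 1 for siPIWI, 5 for the double knockdown, 2 for it against siPIWI and 1 against siPAF1. With 16 libraries siPAF1 gave 22, the double knockdown 36 and that against siPIWI 2, as did no filter (2). Genes higher in cyto alone gave 43 for siPAF1 and 7 for the double knockdown. Without the libraries in doubt the counts were 69, 234 and 9 for the 3 knockdowns, 5 for the double knockdown against siPAF1 and 4 for departure from the sum. With only the compared groups siPAF1 gave 159, the double knockdown 84, and this against siPIWI 0 and against siPAF1 1. The siPAF1 change between fractions (0) gave 3 by the Wald test and 2 with no filter.

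The library number as a replicate block gave 6 for siPIWI, 0 for the double knockdown and 1 for it against siPIWI in NUN, and 7, 76 and 73 for the 3 knockdowns and 1 for the double knockdown against siPAF1 in cyto. All 6 block calls of siPIWI were among the 10, and the 6 siPAF1 calls of cyto were among the 76. Samples share only a number: the deviations of libraries with the same number correlated between -0.41 and 0.77 over group pairs in NUN and between -0.19 and 0.59 in cyto. Of the list tests, 18 calls became 21 with the block and 0 with an estimated correlation or the directional fry test; the mixed fry test called 9. With the block, directional fry called 3 and an estimated correlation 0: with siPAF1 against siGFP in NUN the Paf1 complex and cell cycle lists (adjusted p = 0.047 each), and the cell cycle list in the double knockdown against siPIWI in NUN (0.049).

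Leaving out a library leaves an arm with 1 library, assumed to vary like the other groups. The counts then ranged from 0 to 8 for siPIWI, 0 to 0 for siPAF1 and 0 to 2 for the double knockdown in NUN, and from 0 to 447, 1 to 9 and 1 to 6 in cyto. For the double knockdown in cyto, leaving out a library of the groups outside the comparison, chosen after seeing the data, gave 153 and 156 without a siPIWI library and 1 without a siPAF1 library. For the double knockdown against siPIWI in cyto they ranged from 0 to 52, and for NUN against cyto (5342) from 4372 to 4941. For the double knockdown against the single knockdowns in NUN, against siPAF1 in cyto, for departure from the sum and for changes between fractions they were 0.

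Reversals of direction concerned piwi and atms where the value lay between -0.18 and 0.33. In cyto piwi with siPAF1 (0.00) was at 0.01 with no filter or both strands, 0.04 with the strict filter or only the compared groups, 0.02 with the block, 16 libraries or without the libraries in doubt, 0.21 without the siPAF1 library OSS_146 and 0.03 without the siGFP library OSS_147. In the double knockdown against siPIWI (0.10) piwi was at -0.21 without the libraries in doubt, and it ranged from -0.78 without the double knockdown library OSS_146 to 0.72 without a siPIWI library, with -0.26 without the siPIWI library OSS_147. In NUN piwi in the double knockdown (-0.18) ranged from -0.45 to 0.05, the latter without its library OSS_147. For atms, siPIWI in NUN ranged from -0.16 without the siGFP library OSS_147 to 0.34. The double knockdown against siPAF1 ranged from -0.21 without its library OSS_146 to 0.62 in NUN, and from -0.01 without the siPAF1 library OSS_147 to 0.85 in cyto.

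For 36 values of named genes, under the alternatives that keep all libraries or drop those in doubt, 396 recomputed values kept their direction and their side of the threshold, 15 no longer passed, 22 came to pass and 8 reversed. With a library left out 81 kept both, 53 no longer passed, 2 came to pass and 8 reversed. The 22 were atms in NUN and piwi in cyto, as with piwi in siPIWI at -2.26 (adjusted p = 0.0037) with the block. Adjusted p for CG12691, CG15572, gogo and nimC2 was 0.07 to 0.079 with the block. Over the locus window CG15572 (adjusted p = 0.2), Unc-89 (0.054), Rab27 (0.068) and CG11158 (0.069) no longer passed.

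Of simulated log2 changes of 1 in genes with a mean of at least 20 counts, 8 of 100 were called in cyto and 22 of 100 in NUN. The cyto libraries held 663903 to 1759169 counts, and the biological coefficient of variation was 32% in cyto and 21.2% in NUN; the shares of depth and of variation were not separated.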

Other observations

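The tests of chromosome X were chosen after the result was seen, and the test of neighbouring genes was set before.

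All 5 genes that fell with siPAF1 in cyto besides atms lie on chromosome X. Among genes with lower estimates at an unadjusted p under 0.005, 29 of 76 (38.2%) with siPAF1 in cyto were on X, against 16.5% of the other genes (Fisher's exact test, adjusted p = 4.2e-05 over 12 tests). In the double knockdown of cyto the share was 31 of 78 (39.7% against 16.5%, adjusted p = 1.9e-05), and with siPAF1 in NUN it was 21 of 60 (35% against 17%, adjusted p = 0.0032). The 5 genes that prompted the test are among the 29, so it was repeated with the 6 called genes taken out: the shares were then 24 of 70 (34.3% against 16.5%, adjusted p = 0.0017), 26 of 72 (36.1% against 16.5%, adjusted p = 0.00096) and 20 of 58 (34.5% against 17%, adjusted p = 0.0052). The double knockdown of NUN, which also received siPAF1, did not pass, with 9 of 41 (22% against 17.1%, adjusted p = 0.74). The remaining 8 tests of the first round, of siPIWI and of genes with higher estimates, gave adjusted p of 0.72 to 1. All genes of X together had a median of 0 in the siPAF1 comparison of cyto, against 0.04 elsewhere. The comparisons with siGFP in a fraction share its libraries, so they are not independent, and genes are not independent replicates.

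A hypothesis was that the rise of the 10 siPIWI genes in NUN may spread to neighbouring genes. The 43 tested neighbours within 20000 bases had a median log2 fold change of 0.003 in sense, with 22 of them higher. Of 10000 random sets 4744 had a median as high (one-sided permutation p = 0.47), so no rise in sense of these 43 as a set was seen. The 10 genes were left out of the neighbours. The called pairs Cyp28a5 and nimC2 (574 bases apart) and CG12691 and CG15572 (2031 bases apart) could therefore not count as a spread. Opposite-strand counts did not enter: rk and Cyp313a1, whose opposite strands rose, counted at -1.16 and -0.2. Single neighbours, chosen after their values were seen, had high estimates that did not pass: CG16739 at 3.97 ± 0.68 (adjusted p = 0.12), CG4324 at 3.36 ± 0.84 (adjusted p = 0.54) and CG16741 (adjusted p = 0.16). A median cannot tell whether a few neighbours rose, so a spread to these stays open.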
